A study of Anas platyrhynchos with 6 samples.

How the data were processed

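RNA was extracted with Trizol from flash-frozen liver of laying ducks, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. This kit does not mark strand, so counts of a gene and of a transcript that overlaps it on the other strand cannot be told apart. The values were deposited by the authors as FPKM (counts per kilobase of exon, scaled to the number counted in the library), 1 column per library, for annotated genes and newly assembled genes. The aligner, the counter, the assembler, the genome build and the annotation are not given in the sources used here, and neither is whether reads or fragments were counted. A second table deposited by the authors lists 49205 exons of 15627 transcripts of the 6990 newly assembled genes on 1876 scaffolds, with start and end counted from 1. Positions are given as in that table, and its build is not named.

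Library depth was recovered from the FPKM values. In newly assembled loci with 1 transcript, the FPKM times the exon length was a whole multiple of 1 step per library, which gave each library's total count, from 13415827 to 23584934. With the mean transcript length, rounded, 100% of the values above 0 of the newly assembled genes came out whole within 0.01. For annotated genes, whose lengths are not in the files, the shortest whole length that made all 6 values whole was searched for. The same search on the newly assembled genes returned the length of the exon table in 97.5% and a divisor of it in 2.53%. The exon lengths and counts of annotated genes are therefore known up to a common factor, and their recovered sums came to between 99.5% and 99.6% of the library totals together with those of the newly assembled genes. Limits for a count of 0 are 3 counts, and they cover counting error only. No pair of libraries was a duplicate: chi-square per degree of freedom over genes was between 35.2 and 161 within groups.

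Libraries were grouped by the treatment named in the labels, 3 low ammonia and 3 high ammonia. Nothing says that the libraries came from separate birds, so p-values measure only the spread between these samples, which may be technical, and the room of each group goes with its ammonia level. The main test was limma 3.58.1 in R 4.3.3, with a trend of variance with mean, on log2(FPKM + 1), which understates the change of low genes. Genes with at least 1 FPKM in 3 or more libraries were tested, 2-sided, and called at a Benjamini-Hochberg adjusted p below 0.05, with a further count at an absolute log2 difference of at least 1. Negative binomial count models were not used, because the table holds FPKM and counts could be recovered only up to a common factor per annotated gene. On simulated counts with 100 genes changed at each size in each of 5 runs, over 11790 genes on average and a biological coefficient of variation of 17.7%, the test of high against low ammonia recovered 45.0% of genes changed by a log2 of 1 and 95.6% of those changed by a log2 of 2, and 4.74% of its calls were false. The simulation drew genes independently, around 1 pooled dispersion, with no differences between libraries beyond their totals and the changed genes. These rates may therefore not hold for the real libraries. Correlations between libraries were tested exactly over the 10 splits of 6 libraries into 3 and 3, 1-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

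The tests, their alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Of the 23440 identifiers in the table, 0 matched the gene table used here, which has 26024 genes and no Ensembl identifier in any of them. The planned tests of gene lists and of cell type markers could therefore not be run, and no gene is named by symbol. The rule was to name, per direction, the 12 called genes with the largest log2 difference whose groups did not overlap and whose mean was at least 1 FPKM, together with list members, a fixed set of symbols and the 5 most abundant genes. It was applied without the symbol: 2 annotated genes per direction are given by identifier, since the files do not pair identifiers with names, all 13 called newly assembled loci are given by position, and the 5 most abundant genes are given without identifiers. The genes averaging over 1000 FPKM were singled out after their values were seen. Alternatives tried were pseudocounts of 0.1 and 0.01, no filter on low values, at least 5 FPKM in 3 libraries, median-ratio scaling, limma without the variance trend, and each library left out. Limma voom on the recovered counts, with and without median-ratio scaling, was added after the data were examined.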

Results

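Liver RNA was sequenced from Shanma laying ducks (Anas platyrhynchos) kept in air with little or much ammonia, the irritant gas that builds up from droppings in closed poultry houses. The 176 ducks were chosen at 150 days of age, divided at random between 5 ± 5 ppm (low ammonia) and 75 ± 5 ppm (high ammonia), and exposed for 30 days, from day 200 to day 230. Each group had its own room, so the room and the ammonia level cannot be told apart. The table covered 3 low ammonia and 3 high ammonia libraries and 23440 genes, of which 16450 were annotated and 6990 were newly assembled. The total counts of the low ammonia libraries 1, 2 and 3 were 23584934, 21472246 and 16516390, and those of the high ammonia libraries 1, 2 and 3 were 20491048, 13415827 and 16679497. At these depths a count of 0 in a gene of 1 kb of exon allowed up to 0.127 FPKM in the deepest library and 0.224 FPKM in the shallowest, for counting error only.

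The comparison asked which liver transcripts differed between ducks in high and in low ammonia. Of 11717 genes tested, 48 rose and 44 fell in high ammonia at a Benjamini-Hochberg adjusted p below 0.05 (limma, n = 3 and 3). All 48 genes that rose and 40 of the 44 that fell changed at least 2-fold on the log2(FPKM + 1) scale, and in all 92 the 3 libraries of one group lay apart from the 3 of the other. Groups lay apart in 24.8% of all genes tested, and a small p-value at n = 3 and 3 favours this, so it is no separate support. Genes that rose made up 0.727% ± 0.110 (SD, n = 3) of all FPKM in low ammonia and 2.90% ± 0.173 in high ammonia. Genes that fell made up 7.38% ± 1.35 in low ammonia and 2.51% ± 0.364 in high ammonia. The test chose these genes on the same libraries, so the direction of these shares is given by the choice and is no separate support. With each library divided by its median-ratio factor, which moved the median log2 difference of all genes by 0.126, 74 genes rose and 33 fell, so that 69.2% of calls were rises in place of 52.2%. The number called also depended on single libraries, and it was 56, 33 and 24 without low ammonia library 1, 2 or 3 and 8, 34 and 12 without high ammonia library 1, 2 or 3.

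**Figure D1:**
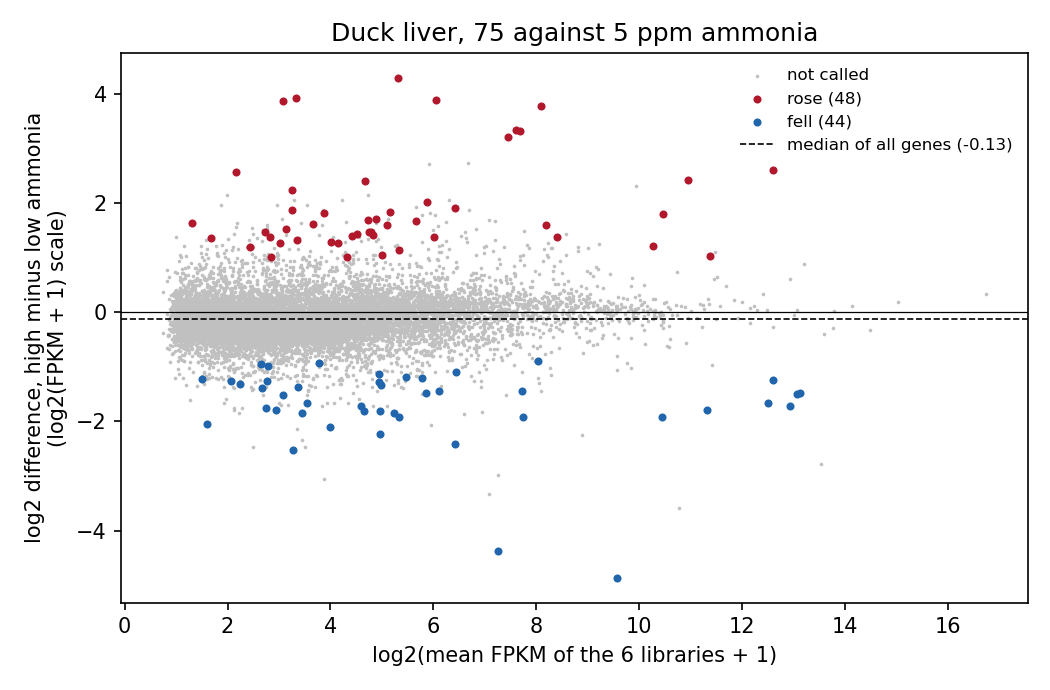
Log2 difference (high minus low ammonia, on the log2(FPKM + 1) scale) of each of the 11717 genes tested against the log2 of its mean FPKM plus 1 over the 6 libraries. Red points are the 48 genes that rose, blue points the 44 that fell and grey points the genes not called, and the dashed line marks the median of all genes at -0.13.

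The files do not pair the gene identifiers with names, and none of them matched the gene table used here, so 2 annotated genes per direction are given by identifier. ENSAPLG00000011408 stood in low ammonia at 0.240 ± 0.114 FPKM (SD, n = 3) from 12 to 30 counts per library, and in high ammonia at 17.8 ± 3.13 FPKM, from 848 to 1654 counts. Its log2 difference was 3.92 (SE 0.18, limma adjusted p = 0.00048), a 74.4-fold ratio of the group means. ENSAPLG00000004090 rose from 7.40 ± 3.32 to 123 ± 51.4 FPKM (log2 difference 3.88, SE 0.36, limma adjusted p = 0.0126). ENSAPLG00000012397 fell from 1477 ± 1230 to 50.5 ± 42.8 FPKM, with a log2 difference of -4.86 (SE 0.74, limma adjusted p = 0.0370). Its low ammonia libraries ranged from 568 to 2876 FPKM and its high ammonia libraries from 16.9 to 98.7 FPKM, and its adjusted p was above 0.05 in 5 of 14 other settings. ENSAPLG00000003647 fell from 293 ± 189 to 11.6 ± 3.56 FPKM (log2 difference -4.37, SE 0.46, limma adjusted p = 0.0172), and its adjusted p was above 0.05 in 4 of 14 other settings.

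**Figure D2:**
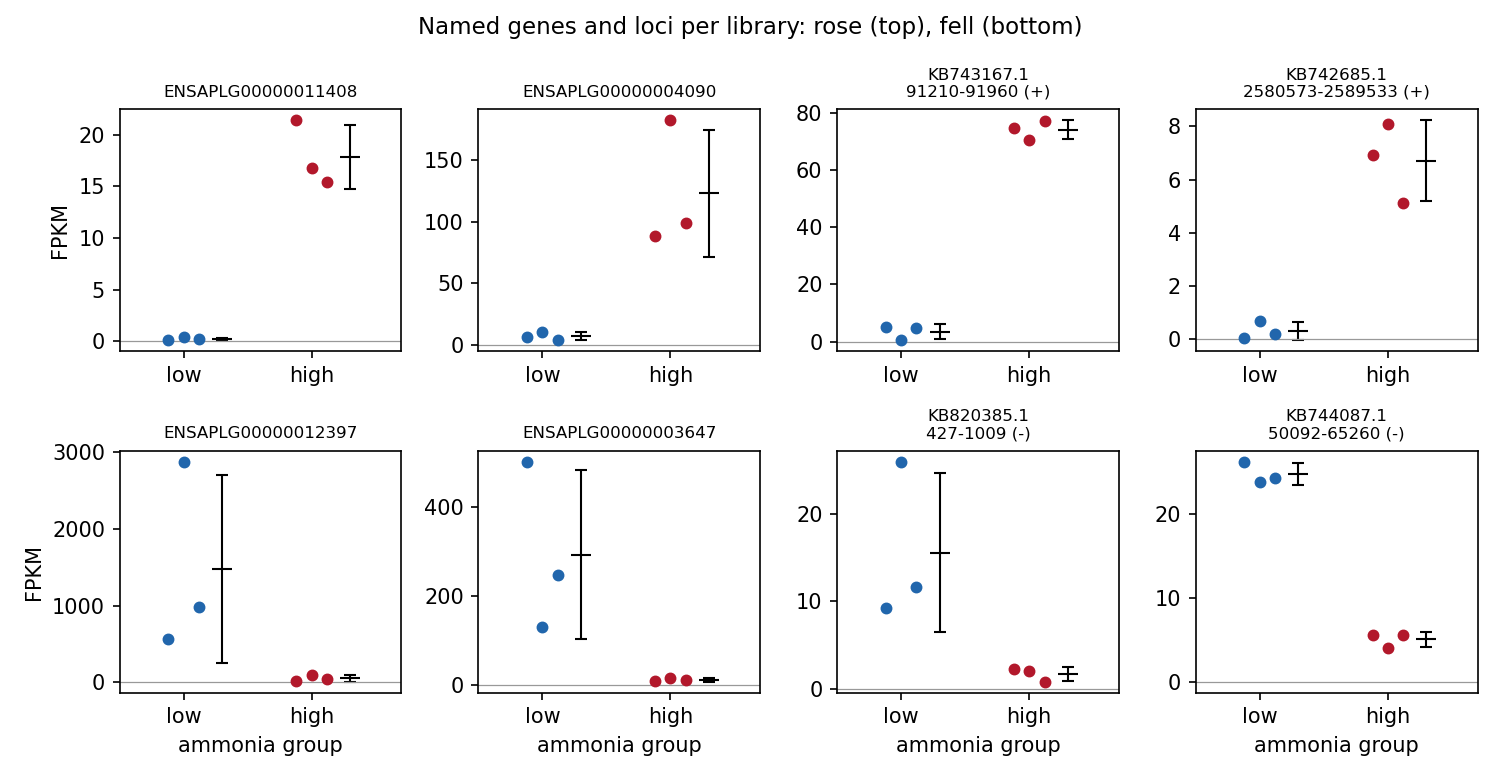
FPKM in each library of the 2 annotated genes and the 2 newly assembled loci with the largest rise (top) and the largest fall (bottom) on the log2(FPKM + 1) scale, which understates the change of low genes, with low ammonia in blue and high ammonia in red. Points are single libraries and the bars beside them are the mean and SD of 3, and in every panel the groups lie apart, as the naming rule required.

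The genes that changed included liver transcripts with a high FPKM. FPKM divides by exon length, so short genes, such as those of 135 and 203 bases called over 1000 FPKM, reach it with a smaller share of the counts than long genes. Of the 103 genes that averaged over 1000 FPKM, 5 rose and 7 fell (11.7%), against 6 and 5 of 814 at 100 to 1000 FPKM, 23 and 18 of 4477 at 10 to 100 FPKM, and 14 and 14 of 6323 below 10 FPKM. The shares called in the lower classes cannot be compared directly with the others, since the log2(FPKM + 1) scale understates the change of low genes. From 100 FPKM up the added 1 changes the values little. The difference between 1.35% called at 100 to 1000 FPKM and 11.7% over 1000 FPKM was not tested. The largest rise in this class was that of an annotated gene with 135 bases of exon, from 1838 ± 694 to 10554 ± 1005 FPKM (SD, n = 3, log2 difference 2.60, SE 0.30, limma adjusted p = 0.0181). An annotated gene of 1344 bases rose from 666 ± 319 to 3297 ± 363 FPKM (log2 difference 2.42, limma adjusted p = 0.0317), and one of 1038 bases rose from 648 ± 210 to 2172 ± 270 FPKM (log2 difference 1.79, limma adjusted p = 0.0309). An annotated gene of 1599 bases fell from 13097 ± 2906 to 4669 ± 674 FPKM (log2 difference -1.48, SE 0.20, limma adjusted p = 0.0280). Annotated genes of 1308 and 2259 bases fell from 12782 ± 3424 to 4451 ± 724 FPKM and from 12084 ± 2933 to 3601 ± 427 FPKM, with log2 differences of -1.50 and -1.73. The remaining 6 genes of this class had log2 differences of 1.03 and 1.21 among those that rose and from -1.25 to -1.93 among those that fell. All 12 kept their direction in the 14 other settings, but 7, 2 and 4 of them passed the threshold without low ammonia library 1, 2 or 3 and 0 without any 1 of the high ammonia libraries, with unadjusted p of at most 0.00210 in those 6 fits. With no filter on low values 0 passed.

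**Figure D3:**
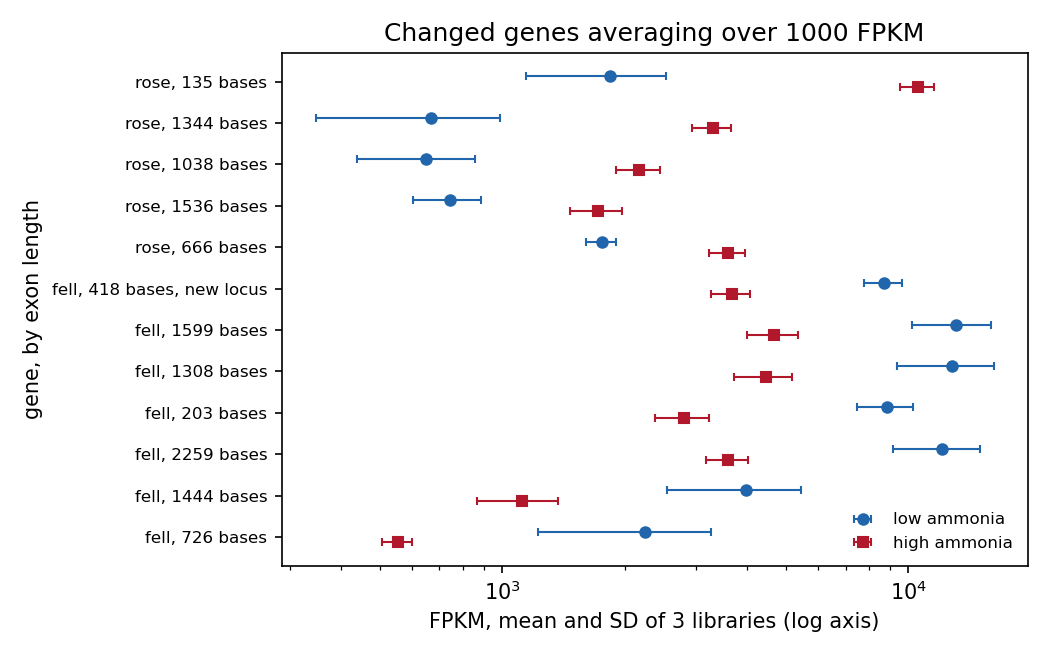
Mean FPKM and SD of 3 libraries (log axis) in low ammonia (blue circles) and high ammonia (red squares) of the 12 genes that averaged over 1000 FPKM and passed the test, each given by its exon length in bases. The 5 genes that rose stand at the top and the 7 that fell at the bottom, and the gene of 1599 bases went from 13097 to 4669 FPKM.

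The 5 genes with the highest mean FPKM did not pass the test. FPKM divides by exon length, so their order is not that of counts. The second gene, of 2301 bases, held 7.27% of counts in low ammonia and 8.09% in high ammonia, against 5.87% and 7.30% for the first. The fifth, of 92 bases, held 0.130% and 0.129%. The first, with 598 bases of exon, stood at 98080 ± 17785 FPKM in low ammonia and 122089 ± 7611 FPKM in high ammonia (SD, n = 3, log2 difference 0.33, SE 0.16, limma adjusted p = 0.351). The next 4 had log2 differences of 0.18, -0.33, 0.11 and 0.01, with limma adjusted p of 0.716, 0.607, 0.695 and 0.982. In each of these 5 genes the ranges of the 2 groups overlapped.

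Newly assembled loci, which the deposited table lists apart from the annotated genes, took 3.66% ± 0.232 of the counts in low ammonia and 3.35% ± 0.174 in high ammonia (SD, n = 3). Of the 1177 that entered the test, 5 rose and 8 fell (1.10%), against 43 and 36 of 10540 annotated genes (0.750%), and these shares did not differ in Fisher's exact test (2-sided p = 0.219, odds ratio 1.48). Whether these loci overlap annotated genes was not analysed here. All 13 had at least 2 exons, as did most of the loci tested, 836 with 2 or 3 exons and 265 with 4 or more. Of the 76 tested loci with 1 exon, limma called 0, with 13 at an unadjusted p below 0.05, against 2013 of all 11717 genes. With 1.10% of tested loci called, 0 of 76 does not tell loci with 1 exon apart from the others. In this class 1 each was called by limma at a minimum of 5 FPKM in 3 libraries, by limma without low ammonia library 1 and by limma voom on recovered counts. Without low ammonia library 1, 2 or 3 the loci called numbered 4 rising and 6 falling, 3 and 2, and 5 and 1, and without high ammonia library 1, 2 or 3 they numbered 0 and 1, 3 and 3, and 1 and 1.

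The locus with the largest rise on the log2(FPKM + 1) scale spanned bases 91210 to 91960 of the plus strand of scaffold KB743167.1, with 2 exons. It went from 3.52 ± 2.56 to 73.9 ± 3.32 FPKM (SD, n = 3, log2 difference 4.29, SE 0.49, limma adjusted p = 0.0181). On the plus strand of KB742685.1, a locus at 2580573 to 2589533 with up to 6 exons rose from 0.310 ± 0.344 to 6.71 ± 1.51 FPKM (log2 difference 2.57, SE 0.25, limma adjusted p = 0.0126). By the ratio of group means the order of these loci was the reverse, at 21.0-fold and 21.7-fold. The other 3 that rose lay at 147796 to 154877 of KB742991.1 (0.205 ± 0.159 to 2.76 ± 0.646 FPKM), at 2 to 1584 of KB820363.1 (16.0 ± 3.86 to 50.2 ± 9.66 FPKM) and at 193707 to 195795 of KB743493.1 (0.803 ± 0.263 to 3.60 ± 0.408 FPKM). Their log2 differences were 1.63, 1.60 and 1.36, with limma adjusted p of 0.0248, 0.0298 and 0.0283. The first locus passed the threshold in 10 of 14 other settings and the one on KB742685.1 in 12 of 14, and the other 3 passed in 7 of 13, 8 of 14 and 6 of 13 of the settings in which they were tested.

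Among the loci that fell, the smallest adjusted p was that of a locus at 50092 to 65260 of the minus strand of KB744087.1, with 5 transcripts of up to 3 exons. It went from 24.8 ± 1.28 to 5.04 ± 0.880 FPKM (SD, n = 3, log2 difference -2.11, SE 0.16, limma adjusted p = 0.00491) and passed the threshold in all 14 other settings. The most abundant one that fell was a 2-exon locus at 224919 to 225469 of the plus strand of KB742399.1, which went from 8704 ± 918 to 3667 ± 395 FPKM (log2 difference -1.25, SE 0.16, limma adjusted p = 0.0228) and passed in 8 of 14. The locus at 427 to 1009 of KB820385.1 fell from 15.6 ± 9.06 to 1.72 ± 0.782 FPKM (log2 difference -2.53, SE 0.39, limma adjusted p = 0.0390) and passed in 6 of 14. The locus with the most transcripts, 17 over bases 1382401 to 1432699 of KB743740.1, went from 9.24 ± 2.25 to 2.10 ± 1.04 FPKM (log2 difference -1.76, limma adjusted p = 0.0435) and passed in 3 of 14. The remaining 4 lay at 48105 to 51882 of KB743099.1, 87 to 445 of KB814285.1, 33470 to 36088 of KB742660.1 and 345503 to 346354 of KB742637.1. By the ratio of group means the first of these fell most of the 8 loci, 23.4-fold, from 3.93 ± 1.19 to 0.168 ± 0.0937 FPKM. The log2 differences of the 4 were -2.05, -1.81, -1.39 and -1.23, with limma adjusted p of 0.0181, 0.0298, 0.0349 and 0.0323, and they passed in 10 of 13, 7 of 14, 6 of 14 and 3 of 13 of the settings in which they were tested.

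Most genes that did not pass the test lay slightly lower in high ammonia. The median log2 difference of the 11717 genes was -0.13 (quartiles -0.34 and 0.08), and 66.3% of genes were below 0. The median was -0.17 below 10 FPKM, -0.11 at 10 to 100 FPKM, 0.06 at 100 to 1000 FPKM and 0.02 above 1000 FPKM. Groups did not overlap in 2904 genes (24.8%, where chance gives 10% on average), of which 716 were higher and 2188 lower in high ammonia. The 9 other splits of the libraries into 3 and 3 gave from 4.57% to 14.8%, the highest with low ammonia library 1 and high ammonia libraries 1 and 3 on one side. After the median-ratio factors these numbers were 1382 and 1366.

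Libraries of the same group were on average closer to each other than libraries of different groups. The mean Pearson correlation of log2(FPKM + 1) across genes was 0.961 within low ammonia, 0.971 within high ammonia and 0.954 between them. Single pairs ranged from 0.959 to 0.963 within low ammonia, from 0.970 to 0.973 within high ammonia and from 0.950 to 0.961 between groups. The ranges within low ammonia and between groups therefore overlapped. The difference of within-group and between-group means was 0.0127, the largest of the 10 ways to part 6 libraries into 3 and 3 (exact permutation p = 0.1, 1-sided, the smallest this design allows). The first principal component held 37.3% of the variance and separated the groups, and the second, with 19.0%, spread the libraries within them.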

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

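The voom tests were added after the data were examined, and the other alternatives were planned. All 92 called genes kept their direction, with an unadjusted p below 0.05, in each of the 14 alternatives in which they were tested. The number past the threshold moved. With no filter on low values, which brought the tested genes from 11717 to 19528, 15 rose and 9 fell, of which 15 and 7 by at least 2-fold. Median-ratio scaling gave 74 and 33, voom on recovered counts 65 and 66, and voom with median-ratio scaling 101 and 43, of which 92 rose by at least 2-fold. At least 5 FPKM in 3 libraries gave 57 and 63. Leaving out 1 library gave from 5 to 28 rising genes and from 3 to 28 falling ones, the same ranges at 2-fold or more. The lowest total, 8, came without high ammonia library 1, followed by 12 without high ammonia library 3, 24 without low ammonia library 3, 33 without low ammonia library 2, 34 without high ammonia library 2 and 56 without low ammonia library 1. These fits have 5 libraries in place of 6.

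Newly assembled loci that rose and fell numbered 3 and 5 with a pseudocount of 0.01, 1 and 2 with no filter, 9 and 7 with median-ratio scaling, 9 and 12 with voom and 11 and 6 with voom and scaling, and from 0 to 5 and from 1 to 6 without 1 library. Of 234 values of the 17 named genes and loci under alternatives, 147 were past the threshold, 87 were not and 0 changed sign. The within-group minus between-group correlation was 0.0661 over the 1000 most variable genes, 0.0139 with Spearman's correlation and from 0.00966 to 0.0169 without 1 library. Why these numbers moved between alternatives was not tested. In 1 of 10 splits of the 6 libraries, the real one, 92 genes were called, and the highest other split called 1. With 10 splits the share cannot fall below 0.1.

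Not run were the gene list tests, for want of matched identifiers, and the negative binomial count models and count filters planned for a table of counts. No paired analysis was possible because the groups share only 1 library number in the labels. In the simulated data, with 3 and 3 libraries, 45.0% of genes changed by a log2 of 1 were recovered, and which part of the loss is due to depth was not tested. Depth limits low genes: a count of 0 in 1 kb of exon allows up to 0.224 FPKM in the shallowest library.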

Other observations

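Tests chosen after the result was seen were the count of calls over other splits and the totals without 1, 10, 50 or 100 abundant genes. So were the groupings of neighbouring loci other than multi-exon loci on opposite strands without overlap, and the values given here without an explanation.

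Among the 7 genes over 1000 FPKM that fell, the SD of the log2 ratio of a pair over the 6 libraries ranged from 0.0527 to 0.707 over the 21 pairs, with a median of 0.313. The lowest was that of the annotated genes with 1599 and 1308 bases of exon, a pair picked for it, whose log2 differences were -1.48 and -1.50. In the next lowest pair the gene with 2259 bases had a ratio to the gene of 1308 bases with an SD of 0.138, and the log2 ratio of the gene of 1308 bases to it went from a mean of 0.08 in low ammonia to 0.30 in high ammonia. A further annotated gene, with 405 bases of exon, stood at 19896 ± 12601 FPKM (SD, n = 3) in low ammonia and 3895 ± 4402 in high ammonia. Its groups did not overlap, yet with a log2 difference of -2.79 (SE 0.80) it missed the threshold in limma (adjusted p = 0.149). An annotated gene of 564 bases went from 3068 ± 1661 to 429 ± 553 FPKM (log2 difference -3.60, SE 0.90, limma adjusted p = 0.117), also without overlap. In both genes the highest value came from low ammonia library 2, and within high ammonia from library 2.

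No gene met the bound set for being switched on or off: 0 genes had a count of 0 in all 3 libraries of one group and at least 10 in each library of the other, and the other splits gave from 0 to 1. Genes with fewer recovered counts were not covered. The low ammonia libraries differed more among themselves than the high ammonia libraries, with a median SD of log2(FPKM + 1) of 0.24 against 0.20 and the larger SD in low ammonia in 59.5% of genes. The mean correlations within the groups, 0.961 and 0.971, differed by more than in any other of the 10 splits (exact permutation p = 0.1, the smallest this design allows).

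The median gene lay lower in high ammonia, by a log2 difference of -0.13, between -0.18 and -0.10 without 1 library, and below 0 in 8 of the 9 pairs of 1 high and 1 low library. Median-ratio scaling, which removes such a shift by construction, brought it to -0.00458, so the pattern depends on the scaling. Lower depth in high ammonia is argued against only as a source of counting error. With every library thinned to 13415827 counts the median was -0.13, a shift between -0.00107 and 0.00199 over the fits without 1 library. Thinning keeps the expected FPKM of each gene, so it cannot test other differences that go with depth. A trend with gene length is argued against as the whole cause, since the medians of the shortest and the longest genes by exon length, of 3 equal classes, were -0.11 and -0.16, and stayed below -0.06 without 1 library. A larger share of a few abundant genes may account for part. With the 20 most abundant genes left out of the totals the median was -0.11. With 1, 10, 50 or 100 left out it was -0.11, -0.08, -0.09 and -0.08. The shift made by leaving out 20 ranged from 0.00391 to 0.0606 without 1 library, which keeps this open. The 917 tested genes of at least 100 FPKM took 74.6% ± 1.79 of the counts in low ammonia and 76.6% ± 1.07 in high ammonia (SD, n = 3). Shares of a fixed total trade off against each other, so this restates the lower values of the less abundant genes and points to no cause. An effect of ammonia or of the room stays open as well, untested.

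Among the newly assembled loci tested, those next to each other on a scaffold had weakly correlated log2 differences across 299 pairs (Pearson r = 0.0959, Spearman rho = 0.0970). The Pearson r lay inside the central 95% of 10000 permutations of positions (-0.113 to 0.114). Untested loci and annotated genes may lie between the members of a pair. Over 9 groupings of these pairs the smallest Benjamini-Hochberg adjusted permutation p was 0.0648 (1-sided), with r = 0.234 for 98 pairs less than 20 kb apart, 0.0487 for 192 pairs farther apart, 0.140 for 149 pairs on the same strand without overlap, 0.737 for 9 overlapping pairs (Spearman rho = 0.333) and 0.813 for the 6 of these on opposite strands. None of the groupings thus passed an adjusted p of 0.05. Counts of loci that overlap on opposite strands cannot be told apart with this kit, so the correlation of these pairs cannot be read as loci changing together. Pieces of 1 transcript assembled as separate loci may lie behind part of the weak correlation. For 112 pairs of multi-exon loci on opposite strands without overlap, which pieces of 1 transcript would not form, r was -0.00272 (permuted range -0.183 to 0.182), but these pairs had a median gap of 92260 bases against 3841 for the close pairs. The 28 of them less than 20 kb apart had r = -0.280 in a permuted range of -0.381 to 0.380, too wide to show a correlation of 0.234, and the 84 farther apart had r = 0.133 (-0.215 to 0.212), so the explanation stays open, and genes are not independent replicates.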
